A study of Mus musculus with 8 samples.

How the data were processed

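The authors' values came from 8 libraries of mouse arcuate nucleus, each made from a pool of 2 mice aged 4 months. Per the labels' protocols, RNA was selected with oligo(dT), made into stranded libraries with the dUTP method and sequenced from both ends for 150 cycles on an Illumina HiSeq instrument. Per the submitters' processing notes, FastQC, cutadapt, HISAT2 2.0.4 and StringTie 1.2.3 were used with the mouse builds mm10 and GRCm38. The settings of these programs, including the strand setting of StringTie, were not stated in the notes. Coordinates are given as the deposited tables list them.

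The authors deposited FPKM (read pairs scaled to transcript length and library size) for each library, computed with Ballgown per the series design text. The deposited log2 columns headed FPKM for a whole group hold the mean of log2(FPKM + 1) over its 2 libraries. The deposited log2 fold change is the difference between those means, and the deposited fold change is its antilogarithm. The deposited p-value equalled that of an ordinary equal-variance test on log2(FPKM + 1) for 100% of the genes and transcripts in each table, and the deposited q-value is an adjustment of it over the table. The tables hold protein-coding genes whose mean FPKM reached 0.5 in at least 1 of the groups compared. They list 13465 genes for the knockout comparison, 13434 for the sponge comparison and 13435 for the comparison of wild type females and males. A library that appears in more than 1 table had the same values in each. The remaining 4 tables repeat the FPKM values and were not used separately. Total read counts per library were not analysed here, so the depth behind each value is unknown and no counting interval is given.

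The following was computed from the deposited FPKM. The genes compared were those with a mean FPKM of at least 0.5 over the 4 libraries of a comparison. limma 3.58.1 was fitted to log2(FPKM + 1) with empirical Bayes moderation and a mean-variance trend, for the 4 libraries of each comparison and without a replicate block. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All tests were two-sided. Values after ± beside a log2 fold change are standard errors, with 2 libraries in each group. The labels do not state that the pools of a group hold separate litters, so the p-values measure the spread between these libraries. These choices, the gene lists and the alternatives described as planned were made before the data were examined.

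The genes named were chosen by a rule. It takes Pomc, Agrp, Npy and Cartpt in each comparison, and the Y-linked genes in each library as a check of the labels. Mir17hg and Xist were also in the rule and were not analysed here. Per comparison it then takes up to 10 called genes with the largest and up to 10 with the smallest log2 fold change, with a mean FPKM of at least 1, an official symbol and both libraries of one group above both of the other. Where fewer than 6 genes passed in a direction, the genes of smallest unadjusted p that met the other conditions were added up to 6, and they are said not to pass. For each gene list that passed, for the arcuate neuropeptide list and for the matching target list, it takes the 2 members of smallest p and the 2 of highest mean FPKM. Genes outside this rule are said to have been chosen after their values were seen.

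The 32 gene lists, written from general knowledge of hypothalamic cell types, pathways and microRNA targets, were tested with camera in limma at a preset correlation of 0.01. Lists with at least 5 tested members entered, and p-values were adjusted over the 30 lists of a comparison. The tests were repeated with an estimated correlation and with fry. The test with an estimated correlation rests on the 2 residual degrees of freedom of a fit with 4 libraries. A list could hardly pass it even where its genes were uncorrelated, so not passing it decides little. Single members were also adjusted over the list alone. For the microRNA seeds, the longest annotated 3' UTR of each gene in GENCODE M21 was searched for 7mer-m8 matches, which include the 8mer matches, of miR-7, miR-17 and miR-20a, miR-18a, miR-19 and miR-92a. The median log2 fold change of genes with a match was set against that of genes without one, and against up to 200 control heptamers of the same composition. The number of exons of a gene is the largest number in any of its transcripts in that annotation. Gene identifiers matched that annotation for 99.8% of the genes in each table. Of the matched genes, 78.37% to 78.47% had the same coordinates there. Exon numbers and 3' UTRs may therefore differ from those of the annotation behind the deposited values.

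The fit was first run on simulated libraries with 200 changed genes, in 5 runs per comparison. The changed genes were drawn only from genes whose mean log2(FPKM + 1) matched an FPKM of 5 or more. Recovery among genes of lower expression was not simulated. For the knockout comparison, simulated on 13155 genes, 0% of 2-fold, 37% of 4-fold and 65.2% of 8-fold changes were recovered, with 4 false calls per run. For the sponge comparison, on 13157 genes, these shares were 0.6%, 43% and 60%, with 3.2 false calls. For the sex comparison, on 13114 genes, they were 0%, 37.9% and 60%, with 2 false calls. A list with a simulated shift was found in 5 of 5 runs in each comparison, at an unadjusted p under 0.05 with camera. Calls among the genes of that shifted list were counted as false calls. The simulated genes varied independently, so correlation between the genes of a list was not covered. Their values were drawn from normal distributions, so genes switching between 0 and a high value were not imitated. In the real libraries, other splits called up to 17 genes for the knockout, 24 for the sponge and 10 for the sex comparison. Neither the adjustment over 30 lists nor a list without a shift was simulated. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.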

Results

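Expression in the arcuate nucleus of the hypothalamus, which holds the POMC and AgRP neurons that control feeding, was measured by RNA sequencing in 4 groups of mice with 2 libraries each. Males lacking the microRNA cluster hosted by Mir17hg (miR-17, miR-18a, miR-19, miR-20a and miR-92a) in Pomc-Cre cells were set against wild type males. Females carrying a miR-7 sponge, a transcript that binds miR-7 and keeps it from its targets, were set against wild type females. The wild type females and wild type males were also set against each other. FPKM summed to between 141666 and 152741 per library, with a median FPKM per gene of 4.51 to 4.85. Between 144 and 192 genes were listed at 0 in a library. Across genes, the correlation of log2(FPKM + 1) had a median of 0.906 for the 4 pairs of libraries from the same group and of 0.909 for the 24 pairs from different groups.

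Pomc was detected in all 8 libraries, and the Y-linked gene Ddx3y, in the 6 libraries where it was analysed, separated males from females. Pomc, the precursor of the melanocortin peptides, was at an FPKM of 33.3 and 14.9 in the knockout libraries and 60.9 and 27.9 in wild type males. It was at 90.4 and 12.4 in the sponge libraries and 37.4 and 71.7 in wild type females. Ddx3y, a Y-linked RNA helicase gene, was at 12.9 and 12.8 in the knockout libraries and 7.12 and 11.0 in wild type males, and was listed at 0 in both wild type female libraries. Ddx3y was not analysed here in the sponge libraries. The deleted cluster and the sponge transcript were also not analysed here, so the manipulations themselves could not be checked.

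**Figure D1:**
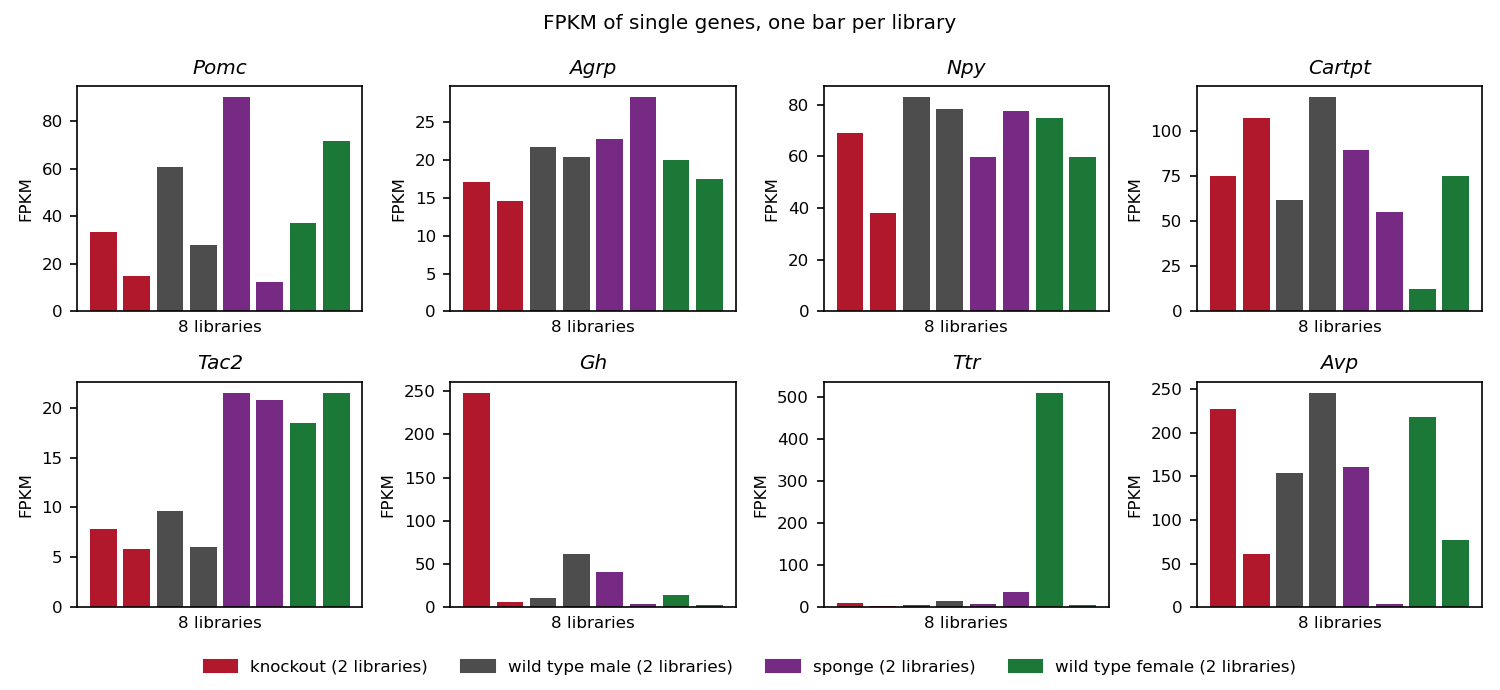
FPKM of Pomc, Agrp, Npy, Cartpt, Tac2, Gh, Ttr and Avp, with 1 bar for each of the 8 libraries, coloured by group. Pomc ranged from 12.4 to 90.4 FPKM, both in sponge libraries, while Tac2 was at 18.5 to 21.5 in the 4 female libraries and 5.83 to 9.60 in the 4 male libraries.

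Genes of the meninges and of fibroblasts were higher as a set in the knockout males, a comparison that asks what the cluster does in POMC neurons. The camera test of that set had an adjusted p of 2.48e-09 at the preset correlation but an adjusted p of 0.775 with an estimated correlation. Ptgds, which encodes the prostaglandin D synthase made by leptomeningeal cells, had an FPKM of 327 and 222 in the knockout libraries and 80.6 and 68.6 in the wild type libraries. The matrix proteoglycan gene Ogn was at 1.63 and 2.65 against 0.39 and 0.15, and Dcn at 12.8 and 4.61 against 1.72 and 5.32. Arcuate neuropeptide and feeding genes were lower as a set, among them Sst, the somatostatin gene, at 2.26 and 1.76 against 3.76 and 3.64. That set had an adjusted p of 0.0217 with camera but an adjusted p of 0.775 with an estimated correlation. Npvf, which encodes the RFamide-related peptides, went the other way, at 13.4 and 10.4 against 5.40 and 5.37.

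All 16 meninges and fibroblast genes tested had a positive fold change in the knockout, with a median log2 of 0.76. In 13 of the 16 genes both knockout libraries lay above both wild type libraries, where chance separates 33.3% of genes over both directions together, and 38.5% of all genes tested were separated in this comparison. With limma, 0 of the 16 passed over all genes tested, 7 were higher at an unadjusted p under 0.05, and 6 passed when adjusted over the list alone. The log2 fold changes were 1.84 ± 0.27 for Ptgds (adjusted p = 0.29), 1.29 ± 0.25 for Ogn (adjusted p = 0.475) and 1.08 ± 0.62 for Dcn (adjusted p = 0.792), with limma. Ptgds lies on chromosome 2 at 25466709 to 25470046 (GRCm38).

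**Figure D2:**
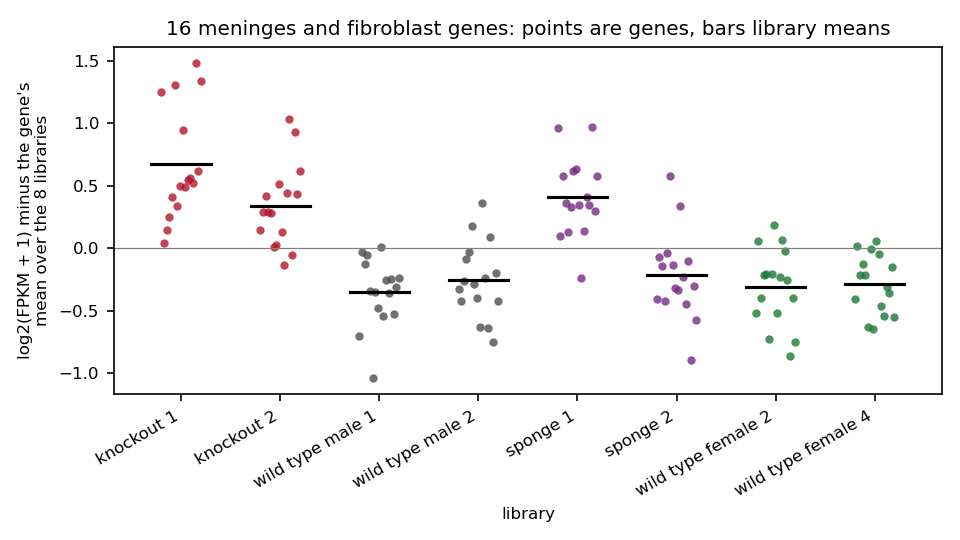
Values of log2(FPKM + 1) of 16 meninges and fibroblast genes less each gene's mean over the 8 libraries, with points for genes and bars for the mean of a library. Before that centring the mean over the list was 2.34 and 2.00 in the knockout libraries and 1.32 and 1.42 in wild type males.

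Of the 37 arcuate neuropeptide and feeding genes, 28 had a negative fold change in the knockout, with a median log2 of -0.30. Left out in turn, knockout replicate 2 and wild type male replicate 1 each left the list short of the threshold, at an adjusted p of 0.429 and 0.522 with camera. With limma, 0 of these genes passed over all genes or when adjusted over the list alone, and 2 were higher and 2 lower at an unadjusted p under 0.05. The log2 fold change was -0.86 ± 0.55 for Pomc, -0.39 ± 0.19 for Agrp and -0.64 ± 0.33 for Npy, each with an adjusted p of 0.792 with limma. Cartpt, the gene of the CART peptide, had 0.06 ± 0.40 (adjusted p = 0.975), Npvf 1.00 ± 0.21 (adjusted p = 0.525) and Sst -0.65 ± 0.20 (adjusted p = 0.792).

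Single genes that passed in the knockout had at most 3 exons and were listed at or near 0 in one group. Pcbp1, a poly(C)-binding protein gene, was at an FPKM of 22.2 and 31.2 in the knockout and listed at 0 in both wild type male libraries. Nhlrc1, which encodes the ubiquitin ligase malin, was at 8.23 and 8.95 and likewise listed at 0 in both wild type libraries. Among the genes that fell, Omg, a myelin glycoprotein gene, was at 0.82 and 0.52 against 17.51 and 16.02, a log2 fold change of -3.42 ± 0.20. Fitm2, a lipid droplet gene, was at 0.06 and 0.12 against 8.93 and 9.86, a log2 fold change of -3.25 ± 0.19. Arl4c, a small GTPase gene, was at 0 and 0.04 against 17.6 and 15.3. The anti-proliferative gene Tob1 was listed at 0 in both knockout libraries against 11.99 and 9.39, and the histone gene Hist1h4i at 0 in both against 24.5 and 18.6.

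In all, 3 genes rose and 5 fell among 13155 genes compared with limma in the knockout, each called gene with an adjusted p of 0.0456 or less, and 701 had an unadjusted p under 0.05 where 658 would be so by chance. Leaving out any 1 of the knockout or wild type libraries left 0 genes passing with limma, with 682 to 1134 at an unadjusted p under 0.05. Omg lies on chromosome 11 at 79500982 to 79504084 and Pcbp1 on chromosome 6 at 86524492 to 86526321 (GRCm38). Of the 8 genes called, 7 had 1 or 2 exons, compared with 5.8% of the genes tested (Fisher's exact test, p = 1.62e-08). Genes added below the threshold included Mgat3 at 23.5 and 26.7 against 2.65 and 1.77 (adjusted p = 0.0654), Spred1 at 25.7 and 28.1 against 6.66 and 6.92 (adjusted p = 0.107), Zxdb at 5.25 and 5.65 against 0 and 0 (adjusted p = 0.0586) and Irf2bp2 at 1.00 and 1.41 against 17.7 and 17.8 (adjusted p = 0.0531). None of these 4 passed with limma.

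Known targets of the deleted cluster did not pass as a set in the knockout. Ctgf, a matrix-associated growth factor gene, was at an FPKM of 1.68 and 1.73 against 1.12 and 0.66, and Hif1a, the hypoxia response gene, at 20.3 and 20.9 against 12.7 and 16.5. App, the amyloid precursor gene, was at 217 and 246 against 238 and 244. Camera gave an adjusted p of 0.457 over 35 targets, of which 23 had a positive fold change, with a mean log2 of 0.07. The log2 fold changes were 0.53 ± 0.21 for Ctgf and 0.48 ± 0.21 for Hif1a, both with an adjusted p of 0.792 with limma, and -0.06 ± 0.21 for App (adjusted p = 0.951). With limma, 0 of the 35 passed over all genes or when adjusted over the list alone, and 0 had an unadjusted p under 0.05.

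No shift was detected in any comparison for genes carrying seed matches in their 3' UTRs. The manipulations were made in POMC neurons, while the libraries held arcuate tissue. A shift confined to those neurons may therefore be too diluted to detect, here and for the literature targets. In the knockout, 1946 of 12954 genes had a match of miR-17 and miR-20a, and their median log2 fold change lay 0.014 above that of the other genes, at the 61st percentile of 200 control heptamers. For miR-18a the difference was -0.043, for miR-19 it was 0.013 and for miR-92a 0.007. In the sponge females 1843 of 12955 genes had a miR-7 match, with a difference of -0.007, at percentile 37.4 of 139 control heptamers. Of the 15 tests of 5 seeds in 3 comparisons, 0 passed with camera, 0 had an unadjusted p under 0.05, and the lowest adjusted p was 0.93, or 0.973 for 8mer sites alone.

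**Figure D3:**
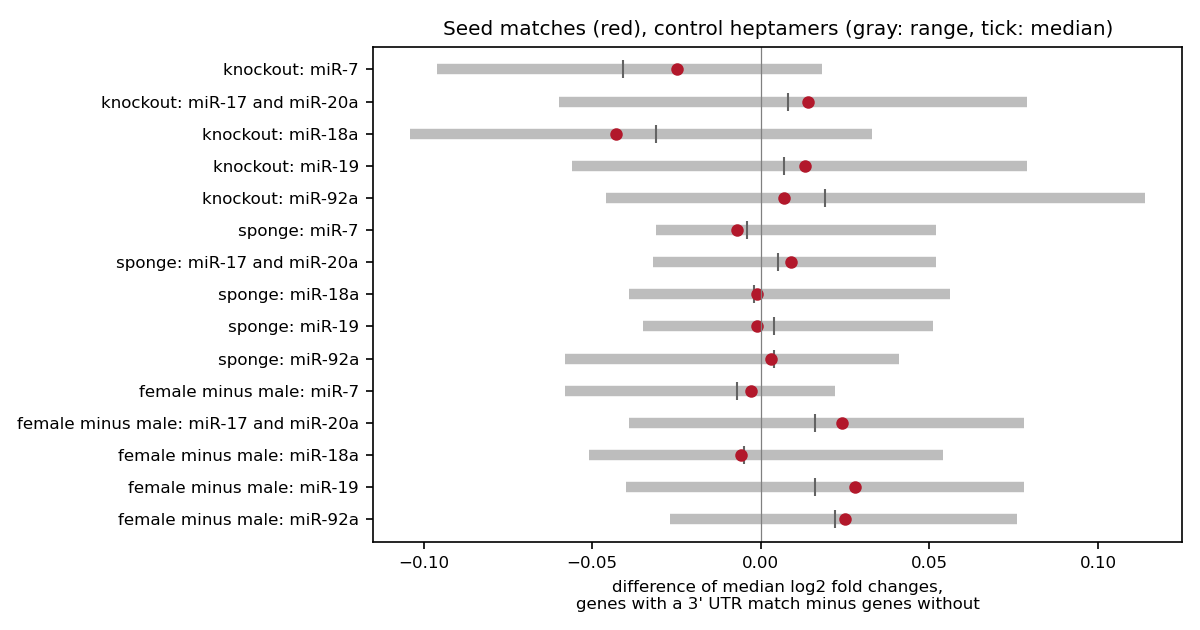
Difference in median log2 fold change between genes with and without a seed match, for 5 seeds in 3 comparisons (red), with the range and median of control heptamers (gray). The difference for miR-7 in the sponge females was -0.007.

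Genes of oligodendrocytes were lower as a set in the miR-7 sponge females, a comparison that asks what titrating miR-7 in POMC neurons does to the arcuate transcriptome, and meninges and fibroblast genes were higher. These sets had adjusted p values of 0.00439 and 0.00205 with camera, but each had an adjusted p of 0.942 with an estimated correlation. That correlation was -0.052 for the oligodendrocyte set, below the preset 0.01, and 0.358 for the meninges and fibroblast set. The unadjusted camera p of the oligodendrocyte set still rose from 0.000293 to 0.0589, so correlated genes do not account for that rise. The mean log2(FPKM + 1) of the meninges and fibroblast genes was 2.08 in sponge replicate 1, 1.45 in sponge replicate 2, and 1.36 and 1.38 in wild type females. Ermn, which encodes a myelin cytoskeletal protein, was at an FPKM of 1.91 and 2.53 in the sponge libraries and 4.67 and 4.54 in wild type females. The myelin genes Mbp and Mal were at 40.7 and 27.0 against 43.0 and 50.6, and at 20.72 and 20.97 against 30.2 and 27.7. Dcn was at 6.00 and 7.30 against 2.37 and 2.60, and Ptgds at 229 and 62.3 against 63.5 and 90.6.

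Of 19 oligodendrocyte genes, 16 had a negative fold change in the sponge females, with a median log2 of -0.34. Of 14 meninges and fibroblast genes, 13 had a positive fold change, with a median log2 of 0.30. Without sponge replicate 1 the adjusted p of these lists became 0.307 and 0.629 with camera. Other cell-type lists went both ways without passing with camera. Mostly negative were 11 of 12 choroid plexus genes (adjusted p = 0.126), 16 of 20 astrocyte genes (adjusted p = 0.559), 15 of 20 pan-neuronal genes (adjusted p = 0.403) and 15 of 20 endothelial and mural genes (adjusted p = 0.559). Mostly positive were 12 of 18 ependymal genes (adjusted p = 0.284), 11 of 16 tanycyte genes (adjusted p = 0.241) and 13 of 18 other arcuate neuron markers (adjusted p = 0.403). Wild type female replicate 2 held the highest values of Ttr, at 510, and of the oligodendrocyte list member Enpp2, at 90.6 against 21.1 in replicate 4, and without it the oligodendrocyte list had an adjusted p of 0.0234 with camera. With limma, 0 oligodendrocyte genes passed over all genes or when adjusted over the list alone (2 lower at an unadjusted p under 0.05), and 0 meninges genes passed over all genes against 1 when adjusted over the list alone (1 higher at an unadjusted p under 0.05). The log2 fold changes with limma were -0.81 ± 0.18 for Ermn (adjusted p = 0.694), -0.45 ± 0.14 for Mal, -0.48 ± 0.26 for Mbp, -0.89 ± 0.76 for Enpp2, 1.13 ± 0.17 for Dcn (adjusted p = 0.356), 0.52 ± 0.30 for Col1a1 and 0.65 ± 0.69 for Ptgds. Without sponge replicate 1 the value for Ptgds was -0.28, and without wild type female replicate 2 that for Enpp2 was 0.14.

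**Figure D4:**
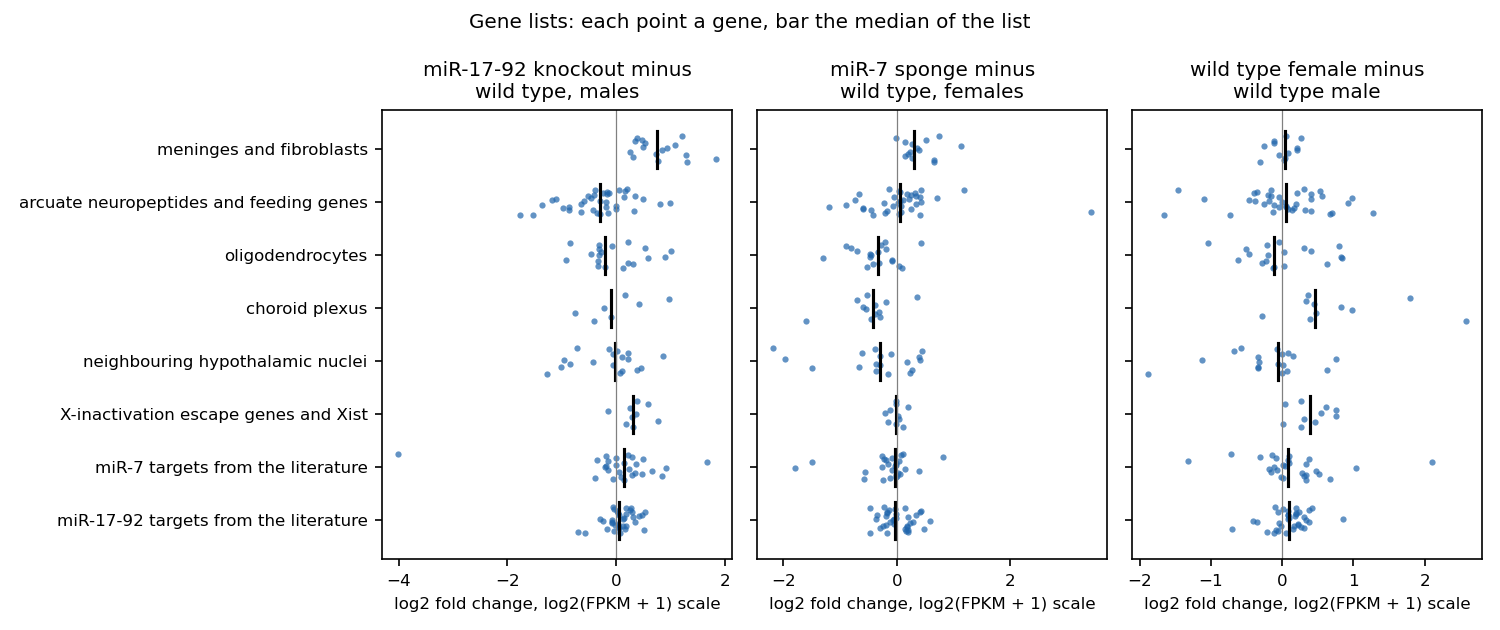
Log2 fold changes of the members of 8 gene lists in the knockout, sponge and sex comparisons, with a point for each gene and a bar at the median of the list. The median of the meninges and fibroblast genes was 0.76 in the knockout and 0.30 in the sponge females.

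Genes that passed in the sponge females were again few-exon genes at or near 0 in one group. Hist3h2ba, a histone gene, was at an FPKM of 32.1 and 32.3 in the sponge libraries and listed at 0 in both wild type female libraries. Hist2h2ac was at 26.7 and 29.2, the transcriptional corepressor gene Irf2bp1 at 15.9 and 17.1, the tubulin cofactor gene Tbcc at 13.0 and 9.90, and Nhlrc1 at 10.01 and 8.67, all listed at 0 in both wild type female libraries. Pnrc1, a nuclear receptor coactivator gene, rose from 1.41 and 1.35 to 29.0 and 22.1, a log2 fold change of 3.47 ± 0.19. Among the genes that fell, Tril, a glial Toll-like receptor modulator gene, was at 13.6 and 13.3 in wild type females and listed at 0 in both sponge libraries, as were Hexim1 against 12.4 and 15.2 and Hist1h4b against 55.1 and 36.6. The potassium channel gene Kcnj16 was at 0.01 and 0 against 11.3 and 13.3, and Ankrd34a at 0.06 and 0 against 7.79 and 8.73.

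In all, 7 genes rose and 7 fell among 13157 compared with limma in the sponge females, each called gene with an adjusted p of 0.0475 or less, and 495 had an unadjusted p under 0.05 where 658 would be so by chance. Leaving out any 1 library left 0 passing with limma, with 691 to 708 at an unadjusted p under 0.05. Tril lies on chromosome 6 at 53815468 to 53820830 and Pnrc1 on chromosome 4 at 33245423 to 33290163 (GRCm38). Of the 14, 13 had 1 or 2 exons, compared with 5.8% of genes tested (Fisher's exact test, p = 9.59e-16). Histone genes have near-identical copies that can share reads, so values of single histone genes are uncertain. Below the threshold, Mtpn was at 5.55 and 4.65 against 37.2 and 44.1, a log2 fold change of -2.77 ± 0.18 (adjusted p = 0.0744 with limma).

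Neither the literature targets of miR-7 nor the arcuate neuropeptide genes passed as a set in the sponge females. Pfn2, the profilin 2 gene and a miR-7 target, was at an FPKM of 16.04 and 20.78 in the sponge libraries and 65.1 and 66.4 in wild type females. Without the sponge it was at 49.1 and 19.9 in the wild type male libraries and 59.5 and 61.2 in the knockout libraries. Yy1 was at 4.93 and 4.52 against 9.31 and 6.14, and Basp1 at 1.37 and 173 against 1.36 and 152. Pomc, Agrp, Cartpt and Npy had log2 fold changes of -0.60 ± 1.04, 0.42 ± 0.19, 1.18 ± 0.93 and 0.02 ± 0.22, each with an adjusted p of 1 with limma. Without sponge replicate 2 the value for Pomc was 0.79 and that for Npy -0.16, and without wild type female replicate 2 that for Cartpt was -0.09. Nmu, the neuromedin U gene, was at 1.40 and 1.65 against 0.96 and 0.80, and the transcription factor gene Isl1 at 5.33 and 5.06 against 4.02 and 3.34.

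Of 27 miR-7 targets, 19 had a negative fold change, with a mean log2 of -0.17 and an adjusted p of 0.326 with camera. The arcuate list had an adjusted p of 0.403 with camera. With limma, 0 of the targets passed over all genes, 1 was lower at an unadjusted p under 0.05, and the same 1, Pfn2, passed when adjusted over the list alone. Its log2 fold change was -1.79 ± 0.19 (adjusted p = 0.18 with limma). That is a fall, whereas targets freed from repression by miR-7 would rise. Yy1 had -0.59 ± 0.24 and Basp1 0.10 ± 3.03, both with an adjusted p of 1 with limma, and Basp1 had -3.00 without sponge replicate 2. Pfn2 lies on chromosome 3 at 57841895 to 57848079 (GRCm38).

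Genes that escape X inactivation were higher as a set in wild type females than in wild type males, a comparison between the control animals of each sex. The set had an adjusted p of 0.0122 with camera but an adjusted p of 0.99 with an estimated correlation. Kdm6a, an X-linked histone demethylase gene, was at an FPKM of 5.45 and 5.98 in females and 2.49 and 3.49 in males. Eif2s3x was at 43.2 and 42.8 against 21.3 and 29.0, and Ddx3x at 59.9 and 42.0 against 26.6 and 39.8. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were listed at 0 in both female libraries and were at 7.12 and 11.0, 4.19 and 6.34, 2.93 and 3.57, and 2.39 and 2.56 in males. Tac2, the neurokinin B gene of the arcuate kisspeptin neurons, was at 18.5 and 21.5 in females and 9.60 and 6.07 in males.

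All 10 X-escape genes tested had a positive female minus male fold change, with a median log2 of 0.38. Without wild type male replicate 2 the adjusted p was 0.0651 with camera. Between the male groups 8 of 9 of these genes were also positive in the knockout, with a median log2 of 0.32 (adjusted p = 0.0666 with camera). The mean log2(FPKM + 1) of the list was 2.30 and 2.46 in knockout males, 2.01 and 2.15 in wild type males, and 2.38 to 2.55 in the 4 female libraries. With limma, 0 of them passed over all genes or when adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05. The 4 Y-linked genes had adjusted p values of 0.0806 to 0.103 with limma, so 0 passed over all genes, 4 had an unadjusted p under 0.05, and 4 passed when adjusted over the list alone. The log2 fold change was 0.76 ± 0.21 for Kdm6a (adjusted p = 0.818), 0.76 ± 0.22 for Eif2s3x (adjusted p = 0.886) and 0.61 ± 0.31 for Ddx3x (adjusted p = 0.92) with limma.

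Choroid plexus genes passed as a set with camera through high values in wild type female replicate 2, with a mean log2 of 0.06 without it, and genes of neighbouring hypothalamic nuclei were lower in females as a set. Both sets had an adjusted p of 0.99 with an estimated correlation. The mean log2(FPKM + 1) of the choroid plexus genes was 3.13 in wild type female replicate 2, 1.60 in wild type female replicate 4, and 1.39 and 1.69 in wild type males. Ttr, the transthyretin gene, was at an FPKM of 510 and 5.03 in females and 4.68 and 14.2 in males, and Clic6 was at 14.6 and 11.8 against 1.80 and 5.01. Col8a1 was at 1.46 and 1.15 against 0.66 and 0.98. Among genes of neighbouring nuclei, Sox14 was listed at 0 in both female libraries against 3.39 and 2.11, and Hmx3 was at 0.31 and 0.63 against 3.19 and 1.44. Pmch, the melanin-concentrating hormone gene, was at 345 and 229 against 112 and 292, and Avp, the vasopressin gene, at 219 and 77.6 against 154 and 246.

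Of 10 choroid plexus genes, 9 had a positive fold change, with a mean log2 of 0.79 and an adjusted p of 0.0424 with camera, or an adjusted p of 0.99 with an estimated correlation. The mean log2 was 0.06 and the adjusted p 0.866 without wild type female replicate 2. Without wild type male replicate 1 or 2 the adjusted p was 0.0773 and 0.243. Of 18 genes of neighbouring nuclei, 10 had a negative and 8 a positive fold change, with a median log2 of -0.07 and a mean of -0.22, and an adjusted p of 0.0336 with camera, or an adjusted p of 0.99 with an estimated correlation. Without wild type female replicate 2 or 4 the adjusted p for that list was 0.222 and 0.158, and without wild type male replicate 2 it was 0.243. With limma, 0 choroid plexus genes passed over all genes or when adjusted over the list alone (1 at an unadjusted p under 0.05), and 0 genes of neighbouring nuclei passed over all genes against 1 when adjusted over the list alone (2 at an unadjusted p under 0.05).

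Single genes that passed between the wild type sexes were of the same few-exon kind. Hist1h4h was listed at 0 in both female libraries and was at an FPKM of 132 and 176 in males, and Mgat2, a glycosyltransferase gene, and Kcnf1, a potassium channel gene, were listed at 0 in both against 14.0 and 14.9, and 9.51 and 11.4. Arl4c was at 0.08 and 0 against 17.6 and 15.3, Hist1h4i at 0 and 0 against 24.5 and 18.6, and Pnrc1 at 1.41 and 1.35 against 22.4 and 21.7, a log2 fold change of -3.28 ± 0.16. Higher in females were Hist1h4b at 55.1 and 36.6 and Igip, an immunoglobulin-inducing peptide gene, at 21.5 and 23.5, both listed at 0 in males. These called genes did not follow sex in the knockout males and sponge females. Hist1h4b was listed at 0 in both sponge libraries, and Igip was at 16.4 and 0. Hist1h4h was at 0 in knockout replicate 1 and 119 in sponge replicate 1, and Kcnf1 at 0 in knockout replicate 2 and 10.55 in sponge replicate 2. Below the threshold, Nceh1 was at 22.9 and 20.8 against 3.45 and 3.97 (adjusted p = 0.0806), Paqr4 at 11.0 and 12.2 against 1.05 and 0.92, Pcbp1 at 22.7 and 39.5 against 0 and 0, and Tmem185b at 6.06 and 5.11 against 0 and 0, the last 3 each with an adjusted p of 0.0679 with limma.

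In all, 3 genes were higher and 6 lower in females among 13114 compared with limma, each called gene with an adjusted p of 0.0389 or less, and 604 had an unadjusted p under 0.05 where 656 would be so by chance. Leaving out any 1 library left 0 passing with limma, with 636 to 891 at an unadjusted p under 0.05. Of the 9 genes called, 8 had 1 or 2 exons, compared with 5.9% of genes tested (Fisher's exact test, p = 1.2e-09). Tac2 had a log2 fold change of 1.27 ± 0.26 and Npvf 0.93 ± 0.19, both with an adjusted p of 0.574 with limma. The arcuate list had an adjusted p of 0.99 with camera, and Agrp, Pomc, Cartpt and Npy had log2 fold changes of -0.16, 0.32, -1.46 and -0.26, with adjusted p values of 0.92 to 0.948 with limma. The control females and males came from different mouse lines, so sex and line cannot be told apart.

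**Figure D5:**
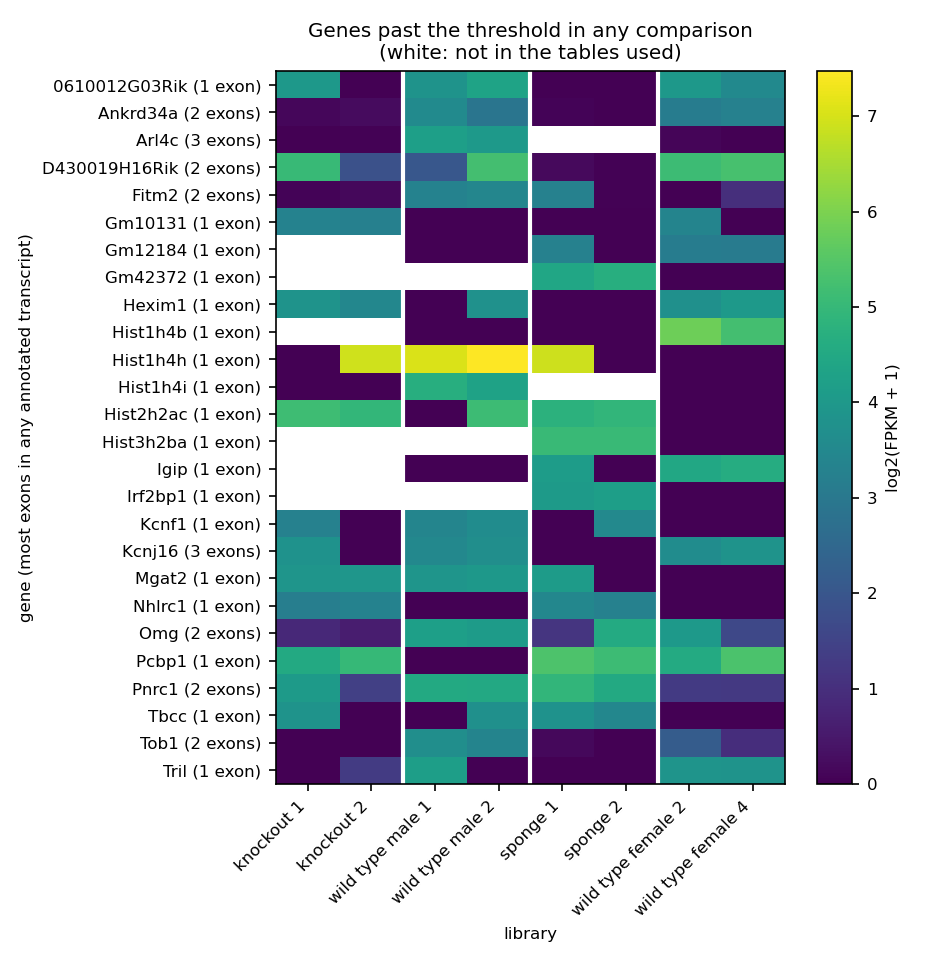
Expression as log2(FPKM + 1), in colour, of the 26 genes past the threshold in any comparison, by library, with the number of exons beside each gene. White cells were not analysed here, and Hist1h4h is at 0 in both wild type female libraries and at 132 and 176 FPKM in wild type males.

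Fold changes in the knockout and in the sponge females were close to uncorrelated across the 12852 genes tested in both, with a Pearson r of 0.017 and a Spearman rho of 0.063. Nhlrc1 passed in both comparisons. Pcbp1, which passed in the knockout, was at an FPKM of 40.4 and 33.7 in the sponge libraries and 22.7 and 39.5 in wild type females, and was listed at 0 in the wild type males alone. Without wild type female replicate 4 the Pearson r was -0.056, and without wild type female replicate 2 it was 0.083. Genes are not independent replicates, and the comparisons share no library.

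The other gene lists did not pass with camera in any comparison where they are not named above. The lowest adjusted p among them was 0.0666 in the knockout, for the X-escape genes, followed by 0.0754 for ependymal cell genes, 0.126 in the sponge females, for choroid plexus genes, and 0.0829 between the sexes, for microglia genes. Literature targets of miR-7 had an adjusted p of 0.457 in the knockout.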

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

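The settings chosen only after the data were seen were the restriction to genes of at least 5 exons or above 0 in every library compared, the leaving out of libraries in the list tests and in the correlation, and the estimated correlation in the seed tests; the others were planned. The count of genes past the threshold in the knockout, 8, was the same without a filter and without a trend, 10 at a mean FPKM of at least 1 and 9 with all 8 libraries in one fit, of which 2 were shared. It was 2 at a pseudocount of 0.1 and 2 with the transcript level tables. With limma it was 0 (701 at an unadjusted p under 0.05) when quantile normalized, 0 (695) with median ratio scaling, 0 (671) for genes with at least 5 exons, 0 (723) for genes above 0 in every library compared, and 0 (845) with an ordinary linear model without moderation. With the sponge the count was 14, and it was 14 without a filter or without a trend, 16 at a pseudocount of 0.1, 13 quantile normalized and 13 with median ratio scaling. It was 1 with an ordinary linear model without moderation, 1 for genes above 0 in every library compared and 2 with all 8 libraries in one fit. With limma it was 0 (420 at an unadjusted p under 0.05) for genes with at least 5 exons and 0 (1012) with the transcript level tables. Between the sexes the count was 9, with 8 at a pseudocount of 0.1, 9 without a filter and 10 at a mean FPKM of at least 1. It was 1 with an ordinary linear model without moderation, and 3 with all 8 libraries in one fit, of which 0 were shared. With limma it was 0 (555 at an unadjusted p under 0.05) for genes with at least 5 exons, 0 (599) for genes above 0 in every library compared and 0 (1274) with the transcript level tables. Fewer genes entered under the restrictions, and the cause of the other losses was not tested.

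Leaving out any 1 library gave 0 genes in each comparison with limma (lowest 0, highest 0), at 682 to 1134 genes in the knockout, 691 to 708 in the sponge females and 636 to 891 between the sexes with an unadjusted p under 0.05. The library left alone in its group was then assumed to vary like the other group, and with fewer libraries fewer calls are expected from the construction of the test.

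With the replicate number as a block in the knockout, 0 genes passed with limma (582 at an unadjusted p under 0.05), compared with 8 without it. The labels do not say that the numbers pair the samples, and deviations of same-numbered libraries had a correlation of 0.001 across genes. No paired analysis was possible because the sponge and wild type female groups, and the wild type groups of the 2 sexes, share only 1 replicate number.

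Of the gene lists, 2 passed in the knockout, 2 in the sponge females and 3 between the sexes. With an estimated correlation 0, 0 and 0 passed, with a lowest adjusted p of 0.775, 0.942 and 0.99, and with fry 0, 0 and 0 passed, with 0.678, 0.3 and 0.144. With 2 residual degrees of freedom, a list could hardly pass at an estimated correlation, so these failures do not show correlated genes. Between the sexes 1 list passed for genes with at least 5 exons and 1 for genes above 0 in every library compared. Leaving out a library gave 1 to 3 lists in the knockout, 0 to 4 in the sponge females and 1 to 4 between the sexes, fewest without wild type male replicate 1, sponge replicate 1 and wild type male replicate 2. The knockout meninges list passed in each of the leave-one-out fits. The cause was not tested.

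Lists and genes that did not pass changed sign in places. The arcuate list between the sexes had a mean log2 of 0.014 while camera, which compares a list with the other genes, pointed lower. The median over all genes tested was 0.062. The mean of the list was -0.023 when quantile normalized, 0.153 for genes with at least 5 exons, 0.045 for genes above 0 in every library compared, and -0.168 to 0.214 with libraries left out. The mean of the list of literature targets of the deleted cluster, in the knockout, ran from -0.007 to 0.151 with libraries left out. The choroid plexus list between the sexes, which passed with camera, had a mean that stayed positive but ran from 0.058 to 1.511. The correlation of knockout and sponge fold changes, 0.017, was -0.002 at a mean FPKM of at least 5, -0.002 at a pseudocount of 0.1, and -0.056 to 0.083 with libraries left out. Log2 fold changes with libraries left out ran, in the knockout, from -0.405 to 0.531 for Cartpt and -0.154 to 0.03 for App. In the sponge females they ran from -1.984 to 0.791 for Pomc, -0.086 to 2.438 for Cartpt, -0.163 to 0.207 for Npy, -3.003 to 3.196 for Basp1, -1.913 to 0.137 for Enpp2 and -0.28 to 1.581 for Ptgds. Between the sexes they ran from -0.23 to 0.868 for Pomc, -0.625 to 5.78 for Ttr, -0.056 to 1.322 for Pmch and -1.319 to 0.165 for Avp. The cause was not tested.

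Of the 644 values recomputed for 88 results on named genes, 495 kept their direction and side of the threshold, 132 kept the direction only, 16 reversed and 1 newly passed. Of 99 values for 11 results on lists, these numbers were 60, 29, 9 and 1. Results that had not passed count as kept when their direction held and they still did not pass. The 132 and the 29 therefore all came from genes and lists that had passed. The 495 and the 60 do not show that results past the threshold were stable. The seed tests passed in 0 of 15 cases with camera also for 8mer sites alone and with an estimated correlation, at a lowest adjusted p of 0.973 and 0.952. Depth could not be varied, since it is unknown.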

Other observations

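The comparison of the 4 female with the 4 male libraries, the tests of genes with few exons, of meningeal tissue and of mouse lines, and all counts of other groupings of the libraries were chosen only after the results were seen.

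Tac2, which encodes neurokinin B in the arcuate neurons that drive gonadotropin release, was higher in all 4 female libraries, at an FPKM of 21.5, 20.8, 18.5 and 21.5, than in the 4 male libraries, at 7.89, 5.83, 9.60 and 6.07. Its log2 fold change was 1.39 ± 0.16 (adjusted p = 0.0244 with limma). Rab3c, a synaptic vesicle GTPase gene, was at 4.08, 6.48, 3.45 and 5.56 in females and 39.1, 46.7, 30.8 and 35.9 in males, and Napb, a vesicle fusion gene, at 10.8, 11.8, 9.64 and 12.4 against 43.7, 48.5, 33.2 and 40.2. Myo7a was higher in females with a log2 fold change of 1.44, and Disp2 lower with -2.05. In 433 genes, or 3.32%, the sexes did not overlap, where chance gives 2.9%. The genes named here were chosen after their values were seen.

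With limma, 4 genes were higher and 7 lower in females among 13025 genes, when the means of both genotypes of each sex were compared over 8 libraries, and 17 passed when genes of at least 5 exons were tested. Only 1 of the 35 ways to split the 8 libraries into 4 and 4 gave as many genes as the real 11, the real one itself, with 8 in the highest other, so chance can be excluded only if the libraries are freely exchangeable. They come in 4 groups of 2, and only 3 splits keep these groups whole, too few for a share under 0.05, with 3 genes in the highest other of these. Few exons are argued against for these 11 genes, since 0 of them had 1 or 2 exons. Only genes listed for both the knockout and the sponge comparison entered. A gene with a mean FPKM below 0.5 in both groups of 1 sex was therefore left out, and genes of few exons of that kind could not be called. Mouse line or cohort rather than sex may account for the 11 genes and cannot be told apart from it, since 0 mouse lines were measured in both sexes.

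Called genes of few exons were listed near 0 in some libraries and well above it in others. Among genes reaching 5 FPKM, 51.4% of those with 1 or 2 exons had a gap of at least 2 log2 units between neighbouring libraries, compared with 0.33% of those with 5 or more exons. A candidate explanation is failed abundance estimates for such genes. Genotype or sex as a general cause of the gaps is argued against for the 260 genes with such a gap, whatever their exon number. On average, 41.7% of them placed libraries of the same group on different sides, where the median over all pairings was 41.0%. Genes with a mean FPKM below 0.5 in both groups of 1 sex were left out, so gaps of that kind were not covered. Omg, for example, was at 1.21 and 22.9 in the sponge libraries and 15.6 and 2.06 in wild type females.

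The meninges and fibroblast genes, higher in knockout males, are not explained by genes of few exons, since the list passed with an adjusted p of 1.03e-10 with camera for genes of at least 5 exons. More meningeal tissue in the dissected pieces may explain them, but the values cannot tell. The list's mean log2(FPKM + 1) was 2.08 and 1.45 in the sponge libraries, a difference of 0.63, the largest within a group. Within the knockout, wild type male and wild type female groups the difference was 0.34, 0.1 and 0.03. Between knockout and wild type males it was 0.80. Ptgds, the list's most abundant gene, was at an FPKM of 229 and 62.3 in those sponge libraries. Other non-neuronal lists went both ways in the knockout and none passed with camera: 16 of 18 ependymal, 15 of 20 endothelial and mural and 7 of 9 pituitary genes were positive, but 7 of 20 astrocyte, 8 of 19 oligodendrocyte, 9 of 20 microglia and 8 of 16 tanycyte genes were. The microglia count holds separate entries of the gene Itgam, with log2 fold changes of 1.45 and -1.56. The knockout itself stays open, since dissection and genotype cannot be told apart with 2 libraries per group. The adjusted p of 0.775 with an estimated correlation cannot decide it, since that camera test rests on 2 residual degrees of freedom.

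For groups of 2 libraries only 3 splits of 4 libraries exist, too few for a share under 0.05. In the knockout 2 of the 3 gave as many genes, with 8 for the real split and 17 for the highest other. In the sponge females 2 of the 3 did, with 14 and 24, and between the sexes 2 of the 3 did, with 9 and 10.

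Single libraries stood apart in genes of neighbouring tissues, chosen after their values were seen. Gh, the pituitary growth hormone gene, was at an FPKM of 248 in knockout replicate 1 and 6.54 in knockout replicate 2, and Prl at 72.5 and 0.78. Ttr was at 510 in wild type female replicate 2 and at 3.47 to 35.4 in the other libraries. Sst was at 187 in sponge replicate 1 and 10.2 in sponge replicate 2, and Avp at 4.2 in sponge replicate 2 and at 60.9 to 246 in the others. Mbp was at 11.3 in wild type male replicate 1 and 57.0 in wild type male replicate 2.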
